A study of Mus musculus with 20 samples.

How the data were processed

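The series holds 20 RNA-seq libraries from the lungs of adult mice of a mixed C57/129 background. The mice were wild type for the arginase 2 gene Arg2 or carried a knockout of it, and lived for 28 days in room air with 21% oxygen or in a chamber with 10% oxygen. Per the labels' protocols, total RNA from snap-frozen lung was depleted of ribosomal RNA and made into libraries with a directional kit that marks the strand. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm10 with TopHat2 and counted per gene with HTSeq. The versions of these tools, the gene annotation and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts of reads per gene symbol. Each table lists 24062 genes and 5 further lines that name no gene, such as reads outside genes and reads with several alignments. Those 5 lines stayed out of library sizes and tests.

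After the summing described next, reads counted in genes made up between 25.4% and 64.2% of the reads in genes or in no gene. There were between 2.34 and 12.4 alignments with several positions for each read counted in a gene. Both extremes of low assignment, 25.4% and 12.4, belong to sample 3 of the wild type room air group. A symbol was found for 99.3% of the listed genes in the RefSeq annotation of GRCm38.p6, the assembly behind mm10, 22550 by symbol and 1352 by an older name, with 160 left unmatched. Coordinates are 1-based positions on GRCm38 from the GENCODE vM21 annotation.

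The labels give 4 pairs of room air libraries that share a number and differ by the letter A or B. What the letters stand for is not stated. By a rule fixed before the data were examined, a pair was summed when its members were each other's nearest library in their group over the 5000 most expressed genes, thinned to a common total of 2936780 counts, and lay on the same side for Xist against Y-linked counts. All 4 pairs met the rule. Their chi-square per degree of freedom was 2.31 to 2.76 between A and B, above sampling noise but below the 5.57 or more to any other number. The 20 libraries thus became 16 samples, 4 per group. No pair of libraries was identical. The labels say that mice of both sexes were used, but all 20 libraries had more Y-linked than Xist counts. Genes on the Y chromosome and Xist and Tsix were left out of the counts of calls. The numbers within a group are taken as separate animals, which the labels imply without stating; the p-values measure the spread between these samples.

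Counts were analysed in R 4.3.3 with edgeR 4.0.16. Library sizes were scaled by TMM, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. This left 15766 genes and removed 8296. All 4 groups entered a single quasi-likelihood fit (glmQLFit, robust) without covariates, and each comparison was a two-sided glmQLFTest with Benjamini-Hochberg adjustment. A gene is called when its adjusted p is under 0.05. The biological coefficient of variation was 15.8%. Values in CPM (scaled counts, as edgeR's cpm function gives them) use the TMM-scaled library sizes. Group values are means with the standard deviation over 4 samples; log2 fold changes carry a standard error taken from the estimate and its F statistic. Principal components were computed on log2 CPM with a prior count of 2. Of the genes tested, 15761 remained in the counts of calls. The median log2 fold change of all genes stayed within 0.05 of 0 in every comparison under each scaling tried, with -0.05 as the extreme, under upper quartile scaling in the knockout against wild type comparison in hypoxia.

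Gene lists for pathways, cell types and other organs were fixed before the data were examined, and 37 of them had at least 3 measured members. They were tested with camera of limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. With that preset, 23 lists passed for hypoxia in wild type, 17 for hypoxia in the knockout, 10 between genotypes in room air, 11 between genotypes in hypoxia and 18 for the difference between the effects. With a correlation estimated from the data, 0 lists passed in any comparison, so each list is described by its members, and its adjusted p with an estimated correlation is printed beside them. At an unadjusted p of 0.05 the estimated correlation kept 7, 6, 0, 2 and 4 lists in the same order. Over all genes tested, 4.98%, 17.0%, 0.076%, 23.0% and 0.50% were called in that order. A list with a share of called members near these values does not stand out.

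Genes named in the text follow a rule fixed at the same time. It takes Arg2, then up to 10 genes with the largest and 10 with the smallest log2 fold change among called genes with a group mean of at least 1 CPM and no overlap between the groups' samples, and 5 each way for the difference between the effects. It adds the 3 called members of each list with the smallest p, or 6 for the lists on arginine metabolism, hypoxia-inducible factor targets, smooth muscle and matrix, and the member with the smallest p of a list without a call. The text names a selection of these. Predicted genes, Rik and pseudogene symbols, receptor segments and small RNAs were counted but not named.

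Of the 88 named genes, 24 share exonic bases with a gene on the opposite strand and 4 with a gene on the same strand in GENCODE vM21. The shared part exceeds 10% of the exonic bases for 6 of them. It is 81.3% for Ikzf5, which overlaps Pstk, 61.5% for Nppa, 25.2% for Nos3, which overlaps Atg9b, 22.7% for Ankrd37, 20.0% for Arg2, which overlaps Vti1b, and 17.8% for Slc26a10, which overlaps B4galnt1. If the counting ignored strand, reads from those parts were left out as ambiguous or not told apart. Hspa1b has a near-identical neighbour, and H3f3b encodes the same protein as another gene and has processed copies, so reads of both could be lost or split.

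Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with sample weights, no filter or a mean of at least 1 CPM, all 20 libraries kept apart, the A libraries alone, a fit on the compared groups only, the replicate number as a block, an added fold threshold and each sample left out in turn. Keeping the 20 libraries apart counts A and B of 1 number as separate replicates. If they come from 1 animal, the p-values of that alternative are too small. Sex as a covariate was planned and could not be fitted, since no library lay on the female side. Further alternatives were chosen after seeing the data: removing each sample's trend with gene GC content, a covariate for reads outside genes, leaving out wild type room air 3 and wild type hypoxia 4, leaving out 4 samples with markers of other organs (wild type room air 1, knockout room air 3 and 4 and knockout hypoxia 1), and leaving out Rn45s and Lars2. Samples with lower levels of such markers stayed in, among them knockout hypoxia 2 for pancreatic genes and wild type room air 2 for skeletal muscle genes.

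The gene test, the list test and the removal of the GC trend were tried on simulated counts for 15766 genes. These were drawn from the real means and library sizes. In the gene test 200 genes with a mean over 1 CPM were changed, so recovery of weaker genes was not measured. No sample was made to stand apart, as wild type room air 3 does in the data. For hypoxia in wild type, edgeR recovered 87% of genes changed 2-fold and 58% of those changed 1.5-fold, with 4 calls on unchanged genes. For knockout against wild type in hypoxia it recovered 90% and 57%, also with 4 such calls. For the difference between the effects it recovered 66% and 16%, with 3 such calls. DESeq2 made more such calls, 31, 19 and 16 in the same order, and limma voom 6, 7 and 3. In the room air comparison, where no gene was changed, DESeq2 made 5 calls and edgeR and limma voom 0. The list test, on a separate draw with the genes of 1 list changed 1.5-fold, found that list and called 0 of 37 unchanged lists. Genes were drawn independently, so false list calls from correlation within lists could not appear. A simulated GC trend, stronger than those seen between the genotypes, gave 970 calls on unchanged genes. Its removal took the rank correlation from -0.71 to 0.0015 and those calls to 9.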

Results

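Gene expression was measured by RNA-seq of ribosome-depleted total RNA in lungs of wild type and Arg2 knockout mice after 28 days in room air (21% oxygen) or hypoxia (10% oxygen). Arg2 encodes the mitochondrial arginase, which splits arginine into ornithine and urea and so draws on the substrate of nitric oxide synthases. Chronic hypoxia raises pulmonary artery pressure in mice, and the series addresses how loss of Arg2 bears on that response. Each of the 4 groups had 4 samples. Reads counted in genes ranged from 9.53e+06 in wild type room air 3 to 6.33e+07 in knockout room air 3. Between 16671 and 18358 genes had at least 1 count. A count of 0 allows up to 0.0474 to 0.315 CPM, depending on the sample and counting error only.

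Arg2 itself lies on chromosome 12 at 79130777 to 79156301 of GRCm38, on the plus strand. It was measured at 9.19 ± 1.92 CPM (SD, n = 4) in wild type room air, 9.30 ± 2.25 in wild type hypoxia, 5.62 ± 1.47 in knockout room air and 4.28 ± 0.91 in knockout hypoxia. The knockout samples thus kept 61.2% of the wild type mean in room air and 46.0% in hypoxia. The log2 fold change between genotypes was -0.70 ± 0.21 (SE) in room air, which did not pass the test (edgeR, adjusted p = 0.0842), and -1.13 ± 0.22 in hypoxia, which did (adjusted p = 0.0019). The position of the deletion is not given in the sources used here, and reads from exons left in place would still be counted, so this is a weak check of the labels. Knockout room air 4, at 7.78 CPM, lay within the wild type range. Hypoxia did not change Arg2 detectably in wild type (log2 fold change 0.04 ± 0.21, adjusted p = 0.951) or in the knockout (-0.39 ± 0.22, adjusted p = 0.24).

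The first 2 principal components of the 5000 most expressed genes held 41.9% and 20.3% of the variance. Hypoxia samples of either genotype lay at 2.52 or higher on the second component and room air samples at 0.11 or lower. On the first component, knockout hypoxia samples lay at -19.7 to -10.0. Wild type room air 3, at -1.26, fell among the knockout room air samples, which ranged from -3.49 to 0.81, while the other wild type room air samples lay at 11.2 to 20.6.

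**Figure D1:**
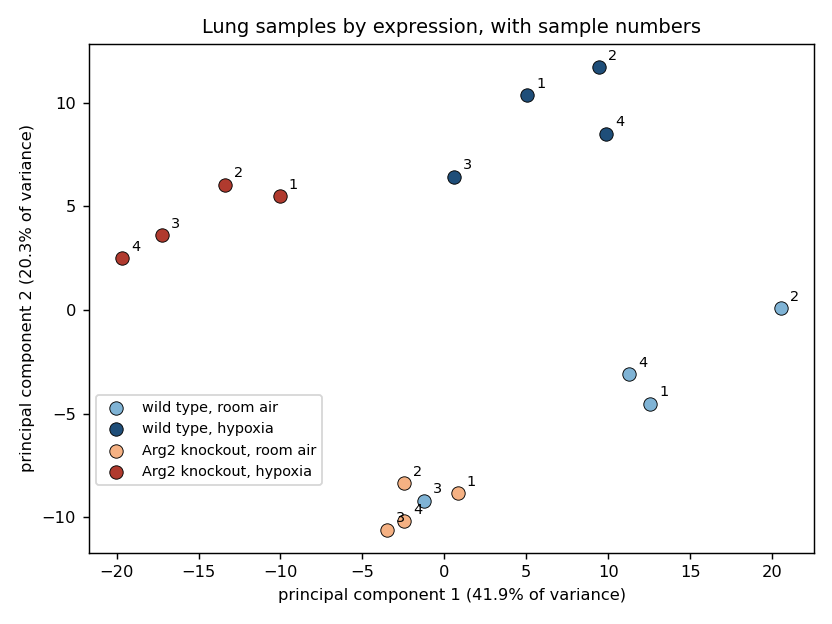
Scores of the 16 lung samples on the first and second principal components (arbitrary units, percent of variance on each axis); colours mark the 4 groups and digits the sample number within a group. Hypoxia and room air separate along the second component, and wild type room air 3 lies among the knockout room air samples.

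Hypoxia in wild type lungs raised genes of the extracellular matrix and lowered markers of lymphocytes. Ntrk2, the receptor of brain-derived neurotrophic factor (chromosome 13, 58806569 to 59133970), rose from 17.1 ± 2.87 to 413 ± 63.2 CPM (log2 fold change 4.60 ± 0.22, adjusted p = 1.67e-09). Cdk19, a kinase of the Mediator complex, rose from 94.5 ± 8.23 to 731 ± 73.2 CPM (2.95 ± 0.13, adjusted p = 2.96e-11), and Slc26a10 from 1.08 ± 0.48 to 20.8 ± 4.44 CPM (4.32 ± 0.29). Plvap, which forms the diaphragms of endothelial caveolae (chromosome 8, 71497765 to 71511752), fell from 321 ± 30.4 to 74.5 ± 6.54 CPM (-2.11 ± 0.15, adjusted p = 1.21e-07). Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, fell from 11.5 ± 1.32 to 1.36 ± 0.69 CPM. The chemokine gene Cxcl12 rose from 257 ± 42.4 to 1148 ± 181 CPM, and Ednrb, an endothelin receptor, fell from 151 ± 25 to 55.6 ± 7.74 CPM.

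Of 36 measured genes of the matrix and its enzymes, 16 rose and 0 fell (22 and 1 adjusted over the list alone; adjusted p = 0.166 with an estimated correlation). Eln, which encodes elastin, rose from 81.7 ± 24.2 to 359 ± 86.9 CPM. Lox, whose product crosslinks collagen and elastin, rose from 40.8 ± 12.8 to 104 ± 12.2 CPM, and the basement membrane collagen gene Col4a1 from 1057 ± 85.3 to 1935 ± 126 CPM. Mmp2 also rose (0.76 ± 0.13), as did Mfap4 of the fibroblast and pericyte list (1.39 ± 0.16; 2 of 20 members rose, 4 and 1 lower adjusted over the list alone, adjusted p = 0.293 with an estimated correlation). Of 20 smooth muscle contractile genes 4 rose, 6 adjusted over the list alone, with Myl9 at 0.55 ± 0.11, Cald1 at 0.55 ± 0.14 and Pcp4l1 at 0.57 ± 0.12 (adjusted p = 0.368 with an estimated correlation). The Cald1 call was lost without the samples with markers of other organs and without wild type room air 4 or wild type hypoxia 1, 3 or 4.

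Among 34 targets of hypoxia-inducible factors, 5 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). Pfkl, a phosphofructokinase, rose by 0.86 ± 0.11 and Ndrg1 by 0.79 ± 0.11 on the log2 scale. Ankrd37 was uneven, at 50.1, 27.8, 7.18 and 7.43 CPM in the 4 hypoxia samples against 2.77 to 4.41 in room air, and its call was lost without the samples with markers of other organs. Vegfa fell from 772 ± 7.66 to 644 ± 10.6 CPM, a call lost in 9 of the alternatives. Of 25 genes of arginine, polyamine and nitric oxide metabolism 2 rose, also 2 adjusted over the list alone: the endothelial synthase Nos3 (0.98 ± 0.12) and the inducible synthase Nos2 (1.45 ± 0.32), with adjusted p = 0.235 for the list with an estimated correlation.

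Of 23 markers of T and natural killer cells 8 fell and 0 rose (16 lower adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), among them the granzyme gene Gzma, from 36.3 ± 8.94 to 15.1 ± 1.18 CPM, and Ccl5, from 13.1 ± 1.49 to 7.03 ± 0.94 CPM. Of 18 B cell markers 7 fell and 0 rose (16 lower adjusted over the list alone; adjusted p = 0.235 with an estimated correlation), including Spib (-1.33 ± 0.20) and Blk (-1.20 ± 0.26). Over both lists 15 members were called lower, but 6 without wild type room air 2 and 22 without wild type room air 3. The endothelial list had 2 higher and 6 lower members of 22, the same when adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). Among 7 lymphatic endothelial genes Prox1, which specifies that cell type, rose from 2.73 ± 0.56 to 7.93 ± 1.74 CPM and the hyaluronan receptor gene Lyve1 fell (-1.59 ± 0.16); 3 rose and 1 fell in all, and as many adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Of 11 skeletal muscle genes 2 fell, 10 adjusted over the list alone (adjusted p = 0.476 with an estimated correlation). One of them, Pvalb, stood at 72.4 CPM in wild type room air 1 and at most at 1.70 in every other sample, and its call was lost in 16 of the alternatives.

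In total 785 of 15761 genes were called, 421 higher and 364 lower in hypoxia, and 234 of them changed at least 2-fold. The count was 484 without wild type hypoxia 1, 400 with a fit on the compared groups only, 1195 with limma voom and 1215 without wild type room air 3 and wild type hypoxia 4.

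In Arg2 knockout lungs the same exposure lowered nearly all measured markers of T, natural killer and B cells and raised chaperone genes. Slc26a10 rose from 0.80 ± 0.24 to 26.7 ± 5.21 CPM (log2 fold change 5.07 ± 0.29, adjusted p = 1.53e-08), and Ntrk2 from 25.7 ± 7.88 to 272 ± 44.2 CPM (3.40 ± 0.20). Rgs5, a regulator of G protein signalling found in pericytes, rose from 7.11 ± 1.23 to 153 ± 23.7 CPM (4.41 ± 0.34, adjusted p = 1.3e-06). The eosinophil chemokine receptor gene Ccr3 fell from 7.09 ± 1.00 to 0.39 ± 0.17 CPM (-4.08 ± 0.41, adjusted p = 2.63e-06), and Ms4a2, a chain of the IgE receptor of mast cells and basophils, from 1.61 ± 0.65 to 0.07 ± 0.06 CPM. Plvap (-2.31 ± 0.15), Cyp1a1 (-3.39 ± 0.31) and Ednrb (-1.51 ± 0.12) fell and Cxcl12 (1.83 ± 0.13) rose.

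Of 23 T and natural killer cell markers 22 fell and 0 rose (23 lower adjusted over the list alone; adjusted p = 0.0678 with an estimated correlation), with Gzma going from 36.6 ± 6.05 to 12.6 ± 3.23 CPM and Ccl5 from 10.9 ± 0.66 to 3.85 ± 0.68 CPM. Of 18 B cell markers 16 fell and 0 rose (18 lower adjusted over the list alone; adjusted p = 0.244 with an estimated correlation), including Blk (-1.79 ± 0.27) and Cxcr5 (-2.15 ± 0.32). Knockout room air 3 and 4 carried the thymocyte gene Dntt at 12.7 and 11.6 CPM, against at most 0.594 in every other sample. The thymocyte list had 5 of 8 members lower, 7 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Without the 4 samples with markers of other organs, 15 T and natural killer cell and 16 B cell markers were called lower. Knockout room air 3 also held 187 CPM of Nppa, the atrial natriuretic peptide gene, against 9.44 to 23.9 in the rest of its group; 6 of 17 heart muscle genes fell, 10 adjusted over the list alone (adjusted p = 0.49 with an estimated correlation), and the Nppa call was lost without that sample.

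Of 22 heat shock and unfolded protein response genes 15 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), rose from 782 ± 92.8 to 1629 ± 213 CPM (1.06 ± 0.13, adjusted p = 1.32e-05). Creld2 rose from 39.1 ± 2.62 to 80.4 ± 5.40 CPM and Sdf2l1 from 20.7 ± 3.10 to 45.1 ± 5.81 CPM. Of 30 cell cycle genes 10 rose and 0 fell, 16 and 1 adjusted over the list alone, with Mki67 at 0.90 ± 0.18 and Cenpf at 1.15 ± 0.22 (adjusted p = 0.399 with an estimated correlation). Without the 4 samples with markers of other organs, 10 heat shock and unfolded protein response genes and 13 cell cycle genes were called higher.

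The matrix list had 14 higher and 2 lower members of 36, 14 and 5 adjusted over the list alone (adjusted p = 0.399 with an estimated correlation), with Col4a1 (0.77 ± 0.10), Lox (0.92 ± 0.15) and Serpine2 (0.73 ± 0.07) higher; it had 8 and 4 without the 4 samples with markers of other organs. Targets of hypoxia-inducible factors had 7 higher and 1 lower of 34, 12 and 4 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Ndrg1 rose from 40.5 ± 6.31 to 121 ± 9.25 CPM, the heme oxygenase gene Hmox1 by 0.76 ± 0.09 and the prolyl hydroxylase gene P4ha2 by 0.88 ± 0.11 on the log2 scale, while Pdk1 fell (-0.42 ± 0.09). Nos3 rose (1.26 ± 0.12) and Ddah1, which degrades an inhibitor of nitric oxide synthases, fell (-0.58 ± 0.10); 2 of 25 arginine list genes rose and 1 fell, as many as when adjusted over the list alone (adjusted p = 0.411 with an estimated correlation). Among smooth muscle genes Myl9 rose (0.54 ± 0.11) and Cnn1 fell (-0.76 ± 0.14); 1 of 20 rose and 3 fell, 3 and 3 adjusted over the list alone (adjusted p = 0.962 with an estimated correlation).

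In total 2685 genes were called, 1251 higher and 1434 lower, and 730 changed at least 2-fold. The balance of the 2 directions depends on the processing: 1078 were higher and 1615 lower with upper quartile scaling. With the GC trend removed 1744 were higher and 1524 lower. The count was 1410 without the 4 samples with markers of other organs and 4097 with limma voom. The pancreatic enzyme genes Pnliprp1 and Ctrl were called higher, but stood at 143 and 79.7 CPM in knockout hypoxia 1, at 11.3 and 7.73 in knockout hypoxia 2 and at 2.54 or below in all other samples.

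Across the 15766 genes tested, the effects of hypoxia in the 2 genotypes, which share no samples, had a Pearson correlation of 0.49 and a rank correlation of 0.40; genes are not independent replicates. Of 555 genes called in both, 550 went in the same direction, 297 higher and 253 lower, where independent lists would share 33.4 and 33.1. The difference between the genotypes was itself called for 16 of the 555.

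**Figure D2:**
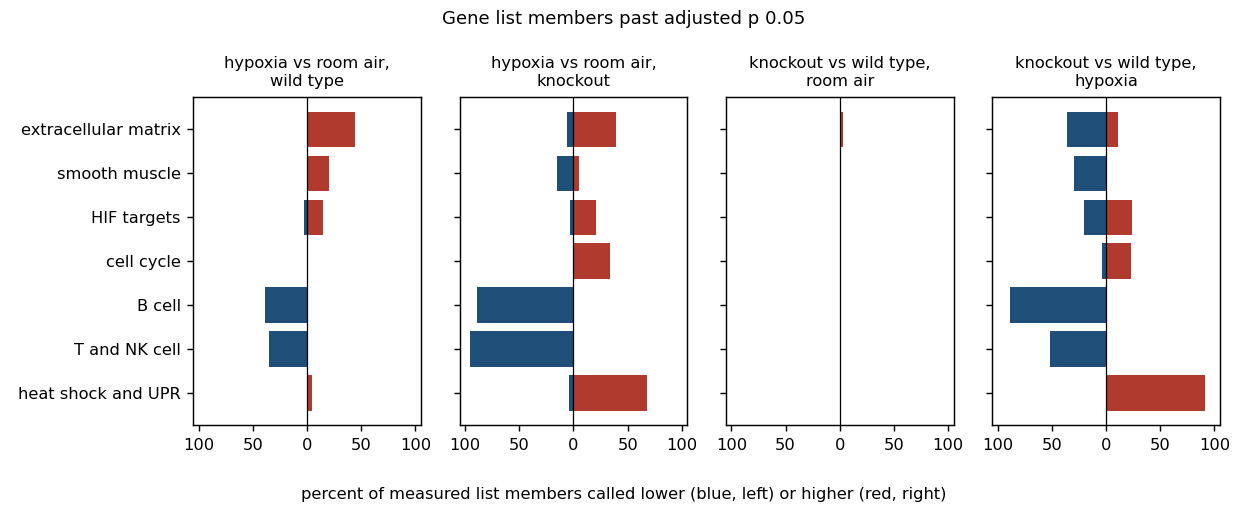
Percent of the measured members of 7 gene lists called higher (red, right) or lower (blue, left) at an adjusted p under 0.05 in each of 4 comparisons (HIF, hypoxia-inducible factor; NK, natural killer; UPR, unfolded protein response). In the knockout against wild type in hypoxia, 20 of 22 heat shock and unfolded protein response genes were higher and 16 of 18 B cell markers lower.

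Between genotypes in room air few genes were called. Mthfd1, a folate enzyme gene on chromosome 12 at 76255298 to 76319803, fell from 137 ± 3.62 CPM in wild type to 97.1 ± 4.03 in the knockout (log2 fold change -0.50 ± 0.08, adjusted p = 0.0273). In hypoxia it was lower in the knockout too, at 89.6 ± 4.76 CPM against 170 ± 20.4 in wild type. Lox rose from 40.8 ± 12.8 to 79.4 ± 8.62 CPM (0.98 ± 0.16, adjusted p = 0.0273), and was the only called member of the 37 lists, also with the matrix list adjusted alone (adjusted p of that list 0.961 with an estimated correlation). Zfand6 (0.69 ± 0.12), Ikzf5 (0.51 ± 0.08), Fam103a1 (0.87 ± 0.15), H3f3b (0.62 ± 0.11), Socs6 (0.48 ± 0.09), Spin4 (0.73 ± 0.13) and Rgs18 (1.01 ± 0.19) rose, and Pmm1 (-0.52 ± 0.10) and Vwa8 (-0.46 ± 0.09) fell. With the GC trend of each sample removed, an alternative chosen after seeing the data, 16 genes were called, but only 6 of these 12. The calls of Rgs18 (0.19), Socs6 (0.17), Ikzf5 (0.22), Spin4 (0.04), Fam103a1 (0.51) and Pmm1 (-0.39) were then lost. The last 2 kept over 50% of their log2 fold change. Each of the named calls was lost in 10 to 17 of 26 alternatives. Among 25 arginine list genes 0 were called (1 higher adjusted over the list alone); the smallest p belonged to the antizyme inhibitor gene Azin1, at 0.64 ± 0.17 (adjusted p = 0.067). The heat shock and unfolded protein response list had 0 called members and 6 higher adjusted over the list alone, led by Creld2 at 0.42 ± 0.10 (adjusted p = 0.0631; adjusted p of the list 0.961 with an estimated correlation). The B cell list had 0 of 18 members called and 4 lower adjusted over the list alone; all 18 were negative, with a median log2 fold change of -0.68 (adjusted p of the list 1.63e-05 with the preset and 0.961 with an estimated correlation). Dntt (3.85 ± 1.03, adjusted p = 0.0741) and Nppa (3.61 ± 1.16, adjusted p = 0.11) did not pass; their means rest on the knockout room air samples named above.

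In total 12 genes were called, 9 higher and 3 lower in the knockout, and 3406 had an unadjusted p under 0.05. DESeq2, which made more false calls than edgeR on simulated counts, called 1119, and limma voom 2079. Without wild type room air 3, in which 25.4% of reads fell in genes against 56.0% to 59.8% in its group, edgeR called 2197 genes, and leaving out any of 7 other samples gave 0. Without that sample and with the GC trend removed, 839 were called.

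In hypoxia many genes were called between genotypes, with chaperone genes higher and lymphocyte markers lower in the knockout. Creld2, a chaperone of the endoplasmic reticulum, stood at 80.4 ± 5.40 CPM in the knockout against 27.5 ± 1.24 in wild type (log2 fold change 1.55 ± 0.10, adjusted p = 3.2e-08), and Hspa5 at 1629 ± 213 against 592 ± 43.1 CPM (1.46 ± 0.13, adjusted p = 2.57e-06). Rgs5 stood at 153 ± 23.7 against 26.3 ± 9.02 CPM (2.54 ± 0.31, adjusted p = 0.000204). Ccr3 (-3.15 ± 0.41, adjusted p = 0.000132) and the lipoxygenase gene Alox15 (-2.64 ± 0.45) were lower, as was Ankrd37 (-2.70 ± 0.52), whose wild type level rested mainly on 2 samples. Pnliprp1 (5.55 ± 1.35) and Ctrl (5.36 ± 1.20) were called higher and rest on the knockout hypoxia samples 1 and 2.

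Of 22 heat shock and unfolded protein response genes 20 were higher and 0 lower, also 20 adjusted over the list alone, with a median log2 fold change of 1.32 (adjusted p = 0.0839 with an estimated correlation). They include Pdia4 of the endoplasmic reticulum (0.77 ± 0.08) and the cytosolic chaperone genes Hsph1 (2.54 ± 0.54), Hspb1 (2.30 ± 0.31) and Hspa1b (4.08 ± 1.09). Hspa1b ranged from 135 to 472 CPM in the knockout and from 3.95 to 46.8 in wild type, and its call was lost without wild type hypoxia 1, 2 or 4 or knockout hypoxia 4. The same knockout hypoxia samples enter this comparison and the previous one on hypoxia.

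Of 18 B cell markers 16 were lower (16 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation), such as Cd22 (-1.01 ± 0.18) and Faim3 (-1.79 ± 0.34). Of 23 T and natural killer cell markers 12 were lower (18 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation), with Ccl5 at -0.88 ± 0.15 and Cd6 at -1.98 ± 0.39. No member of either list was higher. The mean log2(CPM + 0.5) of 11 adipose genes was lower as well, at 1.92 to 2.72 in knockout hypoxia against 2.86 to 3.41 in wild type hypoxia. Less adjoining fat in the knockout hypoxia samples was not told apart from fewer lymphocytes. The matrix list had 4 higher and 13 lower members of 36, 4 and 15 adjusted over the list alone (adjusted p = 0.754 with an estimated correlation). Col6a3 stood at 160 ± 31.6 CPM against 244 ± 20.6 in wild type and Loxl1 at 58.7 ± 8.61 against 89.4 ± 7.14, while Serpine2 was higher (0.35 ± 0.07). Of 20 smooth muscle genes 6 were lower and 0 higher, as many adjusted over the list alone, including Pcp4l1 (-0.69 ± 0.12) and desmin, Des (-0.52 ± 0.14; adjusted p of the list 0.804 with an estimated correlation). The Des call was lost without wild type hypoxia 2 or knockout hypoxia 4.

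Targets of hypoxia-inducible factors went both ways, with 8 higher and 7 lower of 34, the same counts adjusted over the list alone, a median of 0.06 and a mean of -0.02 (adjusted p = 0.88 with an estimated correlation). Ndrg1 (0.91 ± 0.11), P4ha1 (1.25 ± 0.19) and P4ha2 (0.82 ± 0.11) were higher and Pfkl was lower (-0.60 ± 0.11). Of 25 arginine list genes 4 were higher and 2 lower, 4 and 3 adjusted over the list alone (adjusted p = 0.902 with an estimated correlation). Nos3 stood at 70.3 ± 4.24 against 49.3 ± 5.90 CPM, and Gch1, which makes the cofactor of the synthases, at 32.0 ± 2.12 against 22.4 ± 1.27 CPM. Nos2 was lower, at 5.20 ± 0.65 against 11.3 ± 3.47 CPM, a call lost without wild type hypoxia 1 or knockout hypoxia 3 or 4. Among genes tied to pulmonary hypertension and vasoactive signalling 6 of 40 were higher and 2 lower, as many adjusted over the list alone, including Id1, a target of bone morphogenetic protein signalling (1.10 ± 0.12), and the natriuretic peptide clearance receptor gene Npr3 (2.17 ± 0.30; adjusted p of the list 0.853 with an estimated correlation).

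In total 3632 genes were called, 1732 higher and 1900 lower, and 455 differed at least 2-fold. The balance of the 2 directions depends on the processing: 1402 were higher and 2228 lower with upper quartile scaling, and 1770 higher and 1625 lower with the GC trend removed. The count was 2092 without knockout hypoxia 4 and 2364 without knockout hypoxia 3. Across 15631 genes with a GC content, the fold change had a rank correlation of -0.31 with it here and -0.44 in room air; with each sample's GC trend removed, an alternative chosen after seeing the data, 3395 genes were called in hypoxia, 2682 of them among the 3632.

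**Figure D3:**
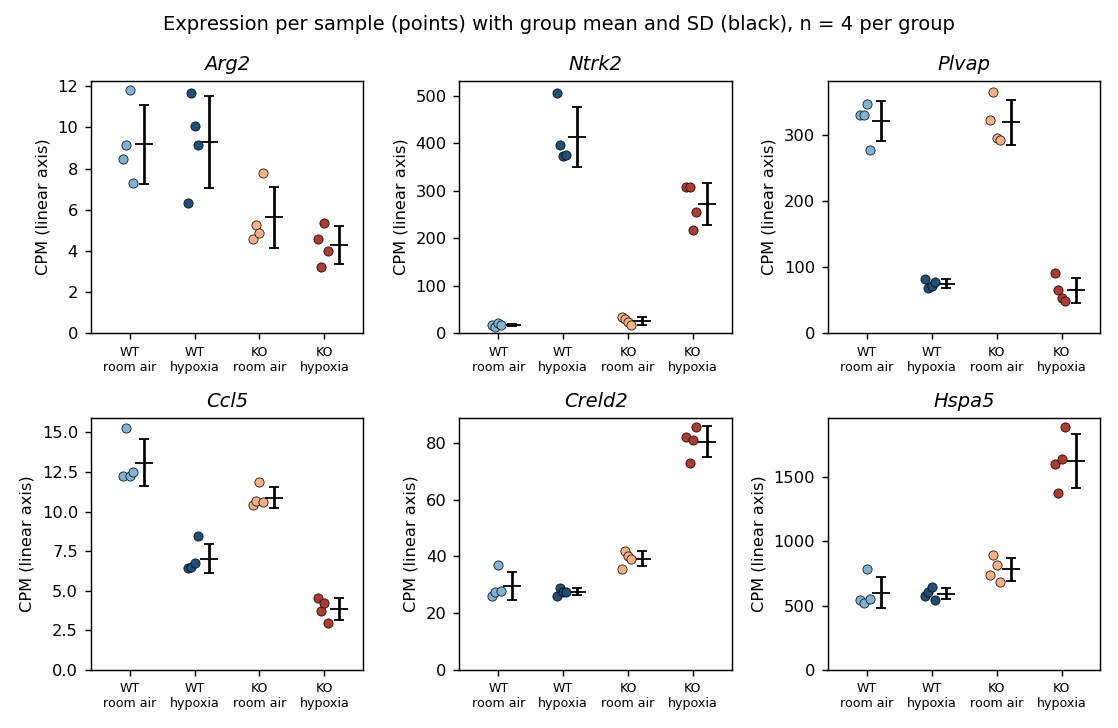
Expression of 6 genes (CPM, linear axis from 0) in each of the 16 samples; points are samples, black bars the group mean and SD (n = 4; WT, wild type; KO, Arg2 knockout). Hspa5 lies between 1374 and 1894 CPM in knockout hypoxia and at 893 or below in all other samples.

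The hypoxia effect itself differed between genotypes for 79 genes, 44 with a higher and 35 with a lower log2 fold change in the knockout. Upper quartile scaling also called 79, of which 35 were higher and 44 lower. Among them, the log2 effect in the knockout exceeded that in wild type by 1.13 ± 0.14 for Creld2 (adjusted p = 0.0015), 1.24 ± 0.20 for Manf, a further stress protein of the endoplasmic reticulum (adjusted p = 0.0081), 1.08 ± 0.18 for Hspa5 (adjusted p = 0.0087) and 0.59 ± 0.12 for the transcription factor gene Xbp1. No rise was called in wild type for these 4 genes, with log2 fold changes of -0.088 for Creld2, -0.11 for Manf, -0.02 for Hspa5 and -0.03 for Xbp1. Of the 22 heat shock and unfolded protein response genes 4 passed, and 14 adjusted over the list alone, all higher (adjusted p = 0.225 with an estimated correlation). Hmox1 (0.74 ± 0.12), Ndrg1 (0.78 ± 0.16) and P4ha2 (0.76 ± 0.16) passed from the 34 targets of hypoxia-inducible factors, with 4 higher and 5 lower adjusted over the list alone (adjusted p = 0.878 with an estimated correlation). The difference was also positive for Id1 (0.86 ± 0.17), Mcf2l (1.38 ± 0.22) and Pmvk (1.42 ± 0.28), which rose in the knockout without a called change in wild type. It was positive as well for Hey1 (1.31 ± 0.24) and the clock gene Ciart (2.37 ± 0.49), which fell in wild type (-0.65 and -1.25) and rose in the knockout (0.67 and 1.12). The wild type room air level of Ciart rests on sample 4, at 17.3 CPM against 3.97 to 5.91 in the other 3 and 2.81 to 3.98 in wild type hypoxia. Wild type room air 3 stood at 98.5 CPM for Hey1, against 56.9 to 63.8 in the other 3. That sample was also the highest of its group for Creld2, Hspa5 and Xbp1, which lowers their wild type log2 fold changes. Of 26 alternatives, the difference was called in 26 for Creld2, 25 each for Hspa5 and Hey1 and 14 for Xbp1.

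The difference was negative for Ccr3 (-3.87 ± 0.53, adjusted p = 0.0024), Ms4a2 (-3.99 ± 0.74), Serpina9 (-1.92 ± 0.31), the T cell gene Themis (-1.83 ± 0.39) and Apobec4 (-2.59 ± 0.54). All 5 fell in the knockout and none had a called change in wild type, where Ccr3 changed by -0.22 and Apobec4 by 0.85. Themis stood at 10.0 and 9.20 CPM in knockout room air 3 and 4, the samples with Dntt, against 4.27 and 4.62 in the other 2. Without the samples with markers of other organs its difference was -1.22 (adjusted p = 0.188). The matrix and smooth muscle lists had 0 called members for this difference, with 0 and 0 matrix genes and 0 higher and 1 lower smooth muscle gene adjusted over the list alone (adjusted p = 0.59 for both with an estimated correlation), so the counts in each genotype do not show that those lists respond differently. The difference for Arg2 did not pass (-0.43 ± 0.30, adjusted p = 0.56). The count was 26 without knockout room air 1, 37 to 48 without wild type room air 4, wild type hypoxia 1 or knockout hypoxia 1, 3 or 4, 48 without the samples with markers of other organs, 125 without wild type room air 1 and 484 with DESeq2. The calls of Pmvk, Ciart, Themis, Apobec4, Xbp1, Ndrg1, P4ha2 and Id1 were each lost in 10 or more of the alternatives.

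Because the mice are of mixed strain, alleles near Arg2 can differ between genotypes. In hypoxia 136 of 542 genes tested on chromosome 12 were called between genotypes, 25.1% against 23% elsewhere (odds ratio 1.12, two-sided Fisher's exact p = 0.254), and 19 of 77 within 5 Mb of Arg2. In room air 1 of the 542 was called (Fisher's exact p = 0.344). That gene was Mthfd1, which lies within 5 Mb of Arg2, where it was 1 of 77 tested (odds ratio 18.7, Fisher's exact p = 0.0573).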

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

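In this part, the tests of wild type room air 3, of a mislabelled sample, of a GC trend behind the room air count, of plasma cells, and of a GC trend and of 1 sample behind the lymphocyte markers in each genotype, and the comparison of these markers with the adipose and blood lists, were chosen after the results were seen.

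The effect of hypoxia differed between genotypes in a direct test for 79 genes, by edgeR. Taking the log2 effect in the knockout minus that in wild type, the difference was positive for Manf (1.24), Creld2 (1.13), Hspa5 (1.08), Xbp1 (0.59), Hmox1 (0.74), Ndrg1 (0.78), P4ha2 (0.76), Id1 (0.86), Hey1 (1.31), Mcf2l (1.38), Pmvk (1.42) and Ciart (2.37). It was negative for Ccr3 (-3.87), Ms4a2 (-3.99), Serpina9 (-1.92), Themis (-1.83) and Apobec4 (-2.59). Of 100 splits drawn from the 16 samples, with the genotypes kept and the exposures mixed within them, 5 gave as many called genes, the real split included. The highest other split gave 460 against the real 79, so chance is not excluded for this count. The 3 highest other splits, with 460, 395 and 217 genes, mixed the wild type exposures and kept those of the knockout. The effect of hypoxia in the knockout thus enters them as a difference between genotypes. The remaining split above the real one, with 97 genes, mixed the exposures in both genotypes, so this does not cover it.

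A sample far from the other 3 of its group was found in 29 of 248 groups of 4 values examined, over the named genes and the library measures; chance alone gives about 1 in 20. Wild type room air 3 had 25.4% of reads in genes and 12.4 alignments with several positions per gene count, and lay apart for Lyve1 (425 CPM), Creld2 (36.8), Hey1 (98.5), Hspa5 (784) and Xbp1 (252). Wild type hypoxia 4 had 19.9% of its gene counts in the ribosomal RNA gene Rn45s, against 0.64% to 0.77% in its group, and lay apart for Ccl5 (8.42 CPM) and Hspb1 (25.7).

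Other samples lay apart for single genes, in CPM: wild type room air 2 for Ccl5 (15.3) and Cyp4b1 (630.4), wild type room air 4 for Ciart (17.3) and Serpina9 (3.59), wild type hypoxia 1 for Cxcl12 (1417) and wild type hypoxia 3 for Hspa1b (46.8). So did knockout room air 1 for Ddah1 (40.03), knockout room air 4 for Pdk1 (55.7) and Mcf2l (135), knockout hypoxia 3 for Serpine2 (142) and Gch1 (28.8), and knockout hypoxia 4 for Xbp1 (375). Genes of other organs stood out in wild type room air 1 (Pvalb, 72.4), knockout room air 3 (Nppa, 187) and knockout hypoxia 1 (Pnliprp1, 143; Ctrl, 79.7). Knockout room air 3 also lay apart for Cenpf (14.7) and Zfand6 (72.7), and knockout hypoxia 1 for Fech (100.3).

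The first pattern weighed is that edgeR called 12 genes between genotypes in room air and 3632 in hypoxia. Without wild type room air 3 the room air count was 2197, while leaving out any other sample gave at most 296, so this sample holds much of the count down. A mislabelled knockout is argued against by Arg2, the targeted gene, at 11.8 CPM in this sample and at most 7.78 CPM in the 8 knockout samples. Arg2 is a weak check, since wild type hypoxia 1, at 6.33 CPM, lay below that knockout value. Mthfd1, within 5 Mb of Arg2, stood at 135 CPM in this sample and at most at 102 CPM in the 8 knockout samples. It was, however, named through its room air call. A GC trend alone hiding the differences is also argued against, since 16 genes were called with the trend removed. With the trend removed and the sample left out 839 were called. The rank correlation of expression, relative to gene means, with gene GC content was -0.25 in this sample. It was -0.31 to -0.19 in knockout room air and 0.22 to 0.48 in the other wild type room air samples. Without this sample the GC trend runs with the genotype in room air, so part of the 2197 may reflect that trend. Of the genes called in hypoxia with the trend removed, 78.6% had the same sign in room air (83.3% without the correction). For the genes called in hypoxia, the median log2 fold change in the direction seen there was 0.19 in room air against 0.49 in hypoxia, 0.13 against 0.45 with the trend removed, and 0.17 against 0.43 with wild type room air 3 left out as well. Since the genes were chosen by their hypoxia call, the hypoxia values are raised by that choice. The spread of 1 low-yield sample and smaller effects in room air are therefore both candidate explanations of the low count, and their shares were not separated. What made the sample differ was not tested. By splits of the 8 room air samples, 3 of 35 gave as many genes as the real 12, and the highest other gave 104, so chance is not excluded. That split put wild type room air 3 with knockout room air 2, 3 and 4 and knockout room air 1 with the other wild type samples, a structure that runs across the groups. For hypoxia 1 of 35 splits, the real one, gave 3632 and the highest other 0, which argues against chance. That share, 1 of 35, is the smallest these splits can give. They cannot tell the genotype from another difference between the same samples.

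The second pattern is the higher level of heat shock and unfolded protein response genes in the knockout in hypoxia. With the GC trend removed 20 of 22 members were called higher, as many as without the correction, which argues against that trend. When any 1 of the 8 hypoxia samples was left out, at least 17 members were called higher, which argues against a single sample. Plasma cells, which are rich in these proteins, would raise their own genes as well, but the plasma cell list without Derl3 had a median log2 fold change of -0.74, with 0 of 5 members higher and 2 lower. Of 35 splits of the hypoxia samples only the real one reached a median of 1.32, and the highest other gave 0.82, which argues against chance. The list is 1 of 37 tested, and 1 of 35 is the smallest share these splits can give. In the camera test with an estimated correlation the list did not pass (adjusted p = 0.0839). Chance is therefore not excluded. The time between death and freezing and other handling of the lungs are not in the labels, and heat shock genes can respond to them. So handling that differed between groups and an effect of the genotype in hypoxia both stay open and untested.

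The third pattern is the lower level of B cell and T and natural killer cell markers in hypoxia in both genotypes. With the GC trend removed 17 members of both lists were called lower in wild type (15 without the correction) and 38 in the knockout (also 38 without), which argues against the trend in each genotype. Lymphoid tissue taken along in knockout room air 3 and 4 is argued against as the whole cause, since without the samples with markers of other organs the median log2 fold change of both lists in the knockout was -1.51 (-1.68 with all samples). A single sample is argued against in the knockout, where at least 37 members were called lower whichever of the 16 samples was left out. In wild type 22 were called without wild type room air 3, with a median log2 fold change of -0.91. Only 6 of the 15 were called without wild type room air 2, while the median went from -0.77 to -0.71. With fewer samples the test is also weaker, so the part of a single sample in the wild type calls cannot be told. The counts called in each genotype are not a direct test of a difference between the genotypes. Fewer lymphocytes in the lung tissue and blood or lymph node left in the samples could both shift these markers. In the knockout 7 of 11 adipose genes were also called lower (median -1.48), as were 4 of 15 platelet and megakaryocyte genes (median -0.68, all 15 negative), while 1 of 14 red blood cell genes was called higher and 0 lower (median 0.22). In wild type these 3 lists had 0 members called lower. Only 1 of 15 platelet and megakaryocyte genes (median -0.20) and 1 of 14 red blood cell genes (median -0.24) was positive there, however. Less adjoining fat with its lymph nodes in the knockout hypoxia samples thus stays open beside fewer lymphocytes. So does less blood in the hypoxia samples of either genotype, and cell counts are not among the data.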

How the results depend on the processing

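In this part, removal of the GC trend, the covariate for reads outside genes, leaving out Rn45s and Lars2 and leaving out named sets of samples were chosen after the results were seen. Direction held under every alternative run on them for each of the 132 named gene values and the 79 list tests that passed with the preset, except those given as reversed below.

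For hypoxia in wild type, 785 genes were called; limma voom called 1195, a fit on the compared groups 400, leaving out wild type room air 3 and wild type hypoxia 4 1215, and a fold of at least 2 left 234 by construction. Leaving out 1 sample gave 484 (wild type hypoxia 1) to 1051 (wild type room air 3). For hypoxia in the knockout, 2685 became 4097 with voom, 1410 without the 4 samples with markers of other organs and 730 at 2-fold. Leaving out 1 sample gave 2011 to 3056. Between genotypes in hypoxia, 3632 became 455 at 2-fold, and leaving out 1 sample gave 2092 (knockout hypoxia 4), 2364 (knockout hypoxia 3) and otherwise up to 4336 (wild type room air 3). Fewer samples in a fit lower its power, but the cause of the other changes was not tested.

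The room air count between genotypes was the least stable. From 12 it became 29 with RLE scaling, 113 with upper quartile scaling, 1119 with DESeq2, 2079 with voom, 20 without a filter, 1704 with 20 libraries kept apart and 207 with the A libraries. The lettered libraries all lie in the room air groups, so the 1704 counts A and B of 1 number as separate replicates. It became 1638 with the covariate for reads outside genes, 2523 without wild type room air 3 and wild type hypoxia 4, 839 with the GC trend removed and wild type room air 3 left out, 0 without the samples with markers of other organs, 4 with the compared groups only and 2 at 2-fold. Leaving out 1 sample gave 0 (wild type room air 1, 2 or 4, wild type hypoxia 3, knockout room air 1, 2 or 3) to 2197 (wild type room air 3), with 296 and 96 without wild type hypoxia 2 and 4, 3 without knockout room air 4 and 6, 1, 4 and 6 without knockout hypoxia 1 to 4. Many genes sit near the threshold, 3406 at an unadjusted p under 0.05; the cause was not tested further.

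For the difference between the effects, 79 became 484 with DESeq2, 256 with voom, 271 with 20 libraries, 214 with the GC trend removed, 139 with the covariate, 129 with the GC trend removed and wild type room air 3 left out, 48 without the samples with markers of other organs and 28 at 2-fold. Leaving out 1 sample gave 26 (knockout room air 1) to 125 (wild type room air 1). It gave 40, 37, 48, 38 and 43 without wild type room air 4, wild type hypoxia 1 and knockout hypoxia 1, 3 and 4. The cause was not tested. With a replicate block the 5 counts were 823, 2714, 238, 3817 and 157, and 78 list tests passed. The 24 same-number pairs correlated at -0.33 to 0.46, 12 of them over 0.1, with a mean of 0.077 against -0.026 for other pairs, and 4 of 16 samples correlated best with their own number. Since not every pair correlated, the numbers were not taken to pair the samples, but a weaker shared structure is not excluded.

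The correlation of the 2 hypoxia effects, 0.49, was 0.38 over genes with a mean of at least 1 CPM, 0.48 with the covariate, 0.43 without wild type room air 3 and wild type hypoxia 4, 0.41 with the GC trend removed and wild type room air 3 left out and 0.37 without the samples with markers of other organs. Of the list tests 79 passed, 70 to 85 when 1 sample was left out and 0 with an estimated correlation, which allows for the correlation within lists. In the list thymocyte, difference of the hypoxia effect between genotypes, the direction reversed without the samples with markers of other organs (adjusted p 0.441). So it did in the list skeletal muscle, difference of the hypoxia effect between genotypes (0.831), whose adjusted p without 1 sample ran from 5.12e-05 (wild type room air 3) to 0.995, reversed, without wild type room air 1, the sample with muscle genes.

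Of the 132 named gene values, 0 lost their call with RLE scaling, 20 libraries or the covariate, 1 with DESeq2, 2 with a replicate block, 3 without Rn45s and Lars2, 7 with the GC trend removed, with that and wild type room air 3 left out, or without wild type room air 3 and wild type hypoxia 4, and 27 without the samples with markers of other organs. When 1 sample was left out, 249 of 2112 such values did. Some of the 132 values, such as that of Arg2 in wild type, were not called and could not lose a call. Upper quartile scaling, voom, the other filters, the A libraries alone and the fit on the compared groups were not run on the named genes. The list tests were not run with upper quartile scaling, DESeq2, voom, the A libraries alone or the compared groups only. Reversed were Spin4 in room air (-0.092, GC trend removed and wild type room air 3 left out), Dntt in room air (-0.58 without the samples with markers of other organs) and Arg2 under hypoxia in wild type, which was not called (-0.053 without wild type room air 4 and -0.088 without wild type hypoxia 2; leaving out any 1 sample gave -0.088 to 0.18). Sex as a covariate was not run, since every library lay on the same side. Depth limits genes of few counts: in wild type room air 3, a count of 0 allows up to 0.315 CPM, and 8296 genes were below the filter.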

Other observations

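In this part, leaving out samples was chosen after the results were seen.

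Several lists of cell types beyond those of the report also moved. After hypoxia in the knockout 8 of 17 ciliated cell genes were called lower (12 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation), but 1 without the samples with markers of other organs. Of 16 club cell genes 4 were lower (5 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation), among them Cyp4b1, which fell in wild type too (-0.89 ± 0.08). Of 11 adipose genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.372 with an estimated correlation), and of 15 platelet and megakaryocyte genes 4 were lower (9 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation). Of 18 immediate early genes 6 were lower in the knockout and 3 in wild type (11 and 6 adjusted over the list alone; adjusted p = 0.397 and 0.293 with an estimated correlation).

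Between genotypes in hypoxia 7 of 14 red blood cell genes were called higher in the knockout (12 adjusted over the list alone; adjusted p = 0.754 with an estimated correlation), with Fech at 0.68 ± 0.20, a call lost in 6 of 26 alternatives. Without wild type room air 3 and wild type hypoxia 4, 1 was called. Of 14 glucocorticoid target genes 6 were higher (8 adjusted over the list alone; adjusted p = 0.754 with an estimated correlation). Of 18 alveolar type II genes 6 were lower and 1 higher, as many adjusted over the list alone (adjusted p = 0.754 with an estimated correlation), led by Etv5 (-0.72 ± 0.09), and of 16 club cell genes 5 were lower, also 5 adjusted over the list alone (adjusted p = 0.827 with an estimated correlation), including the mucin gene Muc5b (-1.62 ± 0.33). Of 22 endothelial genes 9 were higher and 3 lower (9 and 4 adjusted over the list alone; adjusted p = 0.754 with an estimated correlation). Of 18 type 2 inflammation genes 4 were lower and 1 higher, the alarmin gene Il33 at 1.07 ± 0.17 (6 and 1 adjusted over the list alone; adjusted p = 0.754 with an estimated correlation). For the difference between the effects, 1 of 16 circadian clock genes was called, Ciart (2 adjusted over the list alone; adjusted p = 0.291 with an estimated correlation). Between genotypes in room air 0 of the 16 were called over all genes, but 4 were higher and 9 lower adjusted over the list alone, with a median log2 fold change of -0.72 (adjusted p = 0.0318 with the preset and 0.961 with an estimated correlation). The hour at which lungs were taken is not in the labels, so a difference in it between groups stays open and untested.

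Other splits of the samples were counted for the remaining comparisons. For hypoxia in wild type, 2 of the 35 splits of the 8 samples gave as many genes as the real 785, the real one included. The highest other split gave 1101, so chance is not excluded for this count. It exchanged wild type room air 3 with wild type hypoxia 2. By rank correlation of expression, relative to gene means, with gene GC content, its first group held the highest wild type samples, at 0.22 to 0.48. The other wild type samples lay at -0.25 to 0.15. A GC trend across samples may thus enter that count, but the splits were not repeated with the trend removed. For hypoxia in the knockout, 1 of 35 splits, the real one, gave 2685 and the highest other gave 0, which argues against chance. That share, 1 of 35, is the smallest these splits can give.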
